A study of Mus musculus with 6 samples.

How the data were processed

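Islets of 3 WT and 3 bKO samples were profiled by RNA sequencing. Per the labels' protocols, islets were isolated by collagenase digestion, picked by hand, cultured for 2 days in RPMI medium, and used for total RNA extraction. Values are FPKM, and per the labels and design text the authors had a service provider map trimmed reads to the mouse genome and assemble transcripts with Cufflinks under a fixed annotation. The genome build was mm9, per the submitters' processing notes. The aligner and the versions of the upstream tools are not given in the sources used here. The design text also describes log transformation, quantile normalization and removal of genes at 0, but the deposited FPKM values are linear, are not quantile normalized, and include 585 genes at 0 in at least 1 library. The table named 16547 genes. One row with no gene held the 6 column medians and was left out, as was 1 blank row. For 4471 genes the table lists more than 1 transcript with a single value per gene. Unmapped columns numbered 0. The groups and replicate numbers came from the sample titles. Coordinates are not given, because the reference used here for gene names was of another build (GRCm38).

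Genes at 0 in any library were left out, which kept 15962. Values were transformed as log2(FPKM + 1) and quantile normalized over the 6 libraries, and log2 differences are on that scale, which understates the change of low genes. Differences of bKO minus WT were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), and adjusted p-values are Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Means, SD and folds of means are of the deposited FPKM. Intervals are 95%. Quantile normalization assigns the same values to the highest ranks of every library, so Ins1, Ins2 and Iapp were compared on deposited FPKM with exact permutation tests, in a family of 4 tests with the insulin share, for which the adjusted p was 0.2 throughout.

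Before the data were examined, 29 gene lists were fixed, for islet channels, G protein signalling, beta cell state, stress, metabolism and other cell types, and 28 with at least 5 tested genes were tested with camera at a correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in one direction and does not compare the list with other genes. Fits with the mean acinar or stellate score of each library as a covariate, chosen after seeing the data, gave the list mean over the libraries with a 95% interval. The rule for named genes was also fixed then. It takes Kcnj11, then, among genes with adjusted p below 0.05, a mean FPKM of at least 1 and no overlap between groups, the 12 with the largest positive and the 12 with the largest negative differences. In each list it takes up to 4 members with the smallest unadjusted p among those with a mean FPKM of at least 1, and Abcc8, Gnas, Gnaq, Glp1r, Gipr, Ins1, Ins2, Gcg, Sst, Aldh1a3, Mafa and Slc2a2 whatever their p. If fewer than 5 genes passed in a direction, it takes in their place the 12 with the smallest unadjusted p, which was not needed. Iapp, Dgkb and Cdkn2a fall outside the rule and were named after their values were seen. The rule gave 8 higher genes and 18 lower, of which the 12 largest are named. One gene that the rule takes is not reported here.

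Fragments per library were recovered from the steps between low FPKM values of genes with a single transcript, an estimate, since FPKM of Cufflinks need not be whole multiples. The values within 0.1 of a whole number of fragments made up 53.3% to 68.2% per library. Differences between pairs of libraries were set against counting error at these depths, over genes with at least 20 fragments. On simulated libraries that differed by counting alone this ratio was 0.97. The limma steps were tested on simulated data for the comparison of bKO with WT over 15962 genes, with 50 genes changed at each fold. They recovered 56% of 1.5-fold, 86% of 2-fold, 96% of 3-fold and 98% of 4-fold changes, with 11 false among 179 calls. The changed genes were drawn from those of higher expression, and noise was drawn independently for each gene and library. The closeness of bKO replicates 1 and 3 and genes that move together were not simulated, so these rates need not hold for the real libraries. Alternatives were a pseudocount of 0.1, no quantile normalization, median of ratios scaling, no filter on 0, a mean FPKM of at least 1, eBayes without trend, the replicate number as a block, each library left out in turn and, chosen after seeing the data, bKO replicates 1 and 3 averaged as 1 sample. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.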

Results

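RNA from isolated pancreatic islets was sequenced from 2 groups of C57BL/6 mice aged 11 to 12 weeks, with 3 libraries in each group. The control group (WT) carried a floxed Kcnj11 gene. The knockout group (bKO) lacked Kcnj11 in beta cells. Kcnj11 encodes Kir6.2, the pore of the ATP-sensitive potassium channel, which couples glucose metabolism to the membrane potential of the beta cell. Islets hold beta, alpha, delta and PP cells together with vessels and immune cells, and every library is a mixture of these. The values were FPKM, fragment numbers scaled by transcript length and library depth, for 16547 genes. Of these, 15962 were above 0 in all 6 libraries and were tested. The steps between FPKM values of lowly expressed genes put the depth at about 22800000, 26800000 and 24400000 fragments for WT replicates 1, 2 and 3. They put it at about 30100000, 39300000 and 25900000 fragments for bKO replicates 1, 2 and 3. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values below measure the spread between these samples, which may in part be technical.

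The libraries did not differ by genotype alone. Insulin transcripts Ins1 and Ins2 took 36.1%, 37.4% and 29.8% of all FPKM in WT replicates 1, 2 and 3. The share was 27.3%, 33.5% and 26.4% in bKO replicates 1, 2 and 3. The first principal component held 51.1% of the variance and set WT replicate 1, at -32.5, against bKO replicates 1 and 3, at 15.6 and 15.7, with bKO replicate 2 at -2.37. Markers of acinar cells, the enzyme-secreting cells of the exocrine pancreas, had a median of -2.35 in WT replicate 1 on the log2 scale relative to the WT mean. The median was 1.09 and 1.28 in WT replicates 2 and 3 and 1.82, 0.68 and 1.80 in bKO replicates 1, 2 and 3. The profiles of bKO replicates 1 and 3 were closer to each other than those of any other pair, with a Pearson correlation across genes of 0.9986 against 0.9816 to 0.9956 for the 14 other pairs. The mean squared difference of this pair was 1.85 times that of counting error, while the other pairs lay between 17.3 and 115 times. Libraries made from 1 RNA would also differ by more than counting error, so a ratio of 1.85 does not show that the pair are separate samples. The labels do not settle this, and 1 source for both libraries stays open. Both were kept as labelled, so that n = 3 counts libraries. The counts below are also given with the pair averaged as 1 sample, an analysis chosen after the data were seen.

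**Figure D1:**
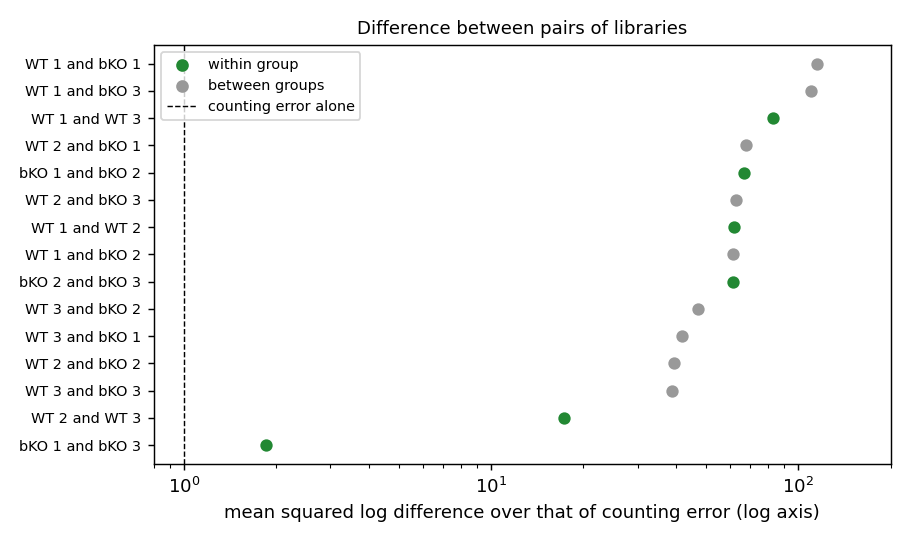
Mean squared log difference between each pair of libraries divided by that of counting error (log axis), for pairs within a group (green) and between groups (grey), with a dashed line at counting error alone. The pair of bKO replicates 1 and 3 lay at 1.85 and the other 14 pairs between 17.3 and 115.

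The comparison of bKO with WT islets asks which transcripts differ between islets of the knockout mice and those of the floxed controls. Kcnj11 itself was measured at 19.7, 24.7 and 25.4 FPKM in WT replicates 1, 2 and 3, and at 3.45, 5.31 and 3.51 FPKM in bKO replicates 1, 2 and 3. Its mean fell from 23.3 ± 3.07 to 4.09 ± 1.06 FPKM (SD, n = 3 each), which left 17.6% of the WT level, and the lowest WT library was 3.72 times the highest bKO library. The log2 difference of FPKM plus 1 was -2.35 (SE 0.17, limma adjusted p = 0.0250). Abcc8, which encodes the sulfonylurea receptor SUR1 that surrounds the pore, was at 173 ± 16.4 FPKM in WT and 184 ± 24.3 in bKO (log2 difference 0.08, limma adjusted p = 0.803). The sign of that difference turned when WT replicate 3 or bKO replicate 2 was left out, with values from -0.03 to 0.16 over the 6 libraries left out in turn. The Kcnj11 call was lost without WT replicate 2 (limma adjusted p = 0.0771), WT replicate 3 (0.0960), bKO replicate 1 (0.228) or bKO replicate 3 (0.175), and with bKO replicates 1 and 3 averaged (0.211), while its log2 difference stayed between -2.52 and -2.26.

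Across the genome, 10 genes were higher and 21 were lower in bKO islets. Among the genes that rose and had a mean FPKM of at least 1, the largest change was in Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells, from 7.70 ± 2.06 to 29.3 ± 0.54 FPKM (SD, n = 3 each; log2 difference 1.76, limma adjusted p = 0.0306). Cd81, a tetraspanin of the cell surface, rose from 81.8 ± 4.06 to 137 ± 6.34 FPKM, 1.68-fold, and Gadd45b, a stress-induced gene, rose from 11.5 ± 0.15 to 18.9 ± 0.92 FPKM, 1.65-fold. Vessel genes were among the other genes that rose. Gpihbp1, which carries lipoprotein lipase across capillary endothelium, rose 1.83-fold from 15.0 ± 0.73 to 27.5 ± 1.44 FPKM. Cd34 rose 1.72-fold, Dll4, a Notch ligand of endothelial tip cells, rose 1.52-fold, and Egfl7, secreted by endothelial cells, rose 1.48-fold. Rgcc, a regulator of the cell cycle, rose 1.82-fold to 7.04 ± 0.30 FPKM. The adjusted p of these 8 genes lay between 0.0306 and 0.0446 in limma.

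Pdyn, the precursor of dynorphin peptides, fell from 228 ± 18.5 to 90.7 ± 0.74 FPKM (SD, n = 3 each; log2 difference -1.35, limma adjusted p = 0.00365), the smallest p of the comparison. Vgf, a granule protein cut into neuropeptides, fell from 70.9 ± 17.6 to 28.9 ± 0.25 FPKM. For Vgf, 4 of the alternative settings that kept all 6 libraries, 3 scaling or filtering choices and eBayes without a trend, put its adjusted p between 0.0541 and 0.0642. With the replicate number as a block, which also kept all 6 libraries, its limma adjusted p was 0.1445. In that fit 0 genes were called, so every gene named here lost the threshold. Grin1, the obligate subunit of NMDA receptors, fell from 8.11 ± 0.50 to 3.21 ± 0.42 FPKM, and Nrcam, a neuronal adhesion molecule, from 9.59 ± 1.53 to 4.21 ± 0.25 FPKM. Rit2, a small GTPase of neurons, fell by 1.20 on the log2 scale, to 0.83 ± 0.14 FPKM, and Scrt1, a zinc finger repressor of neuroendocrine cells, from 8.48 ± 0.86 to 4.63 ± 0.34 FPKM. Enpep, an aminopeptidase that cleaves angiotensin, and Ttyh1, a membrane protein of the tweety family, had log2 differences of -0.92 and -0.90. Reps2, C330027C09Rik and Lrrc24 had log2 differences of -0.73, -0.72 and -0.71. Lrrc24 missed the threshold without quantile normalization (limma adjusted p = 0.0527) and with median of ratios scaling (0.0501).

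**Figure D2:**
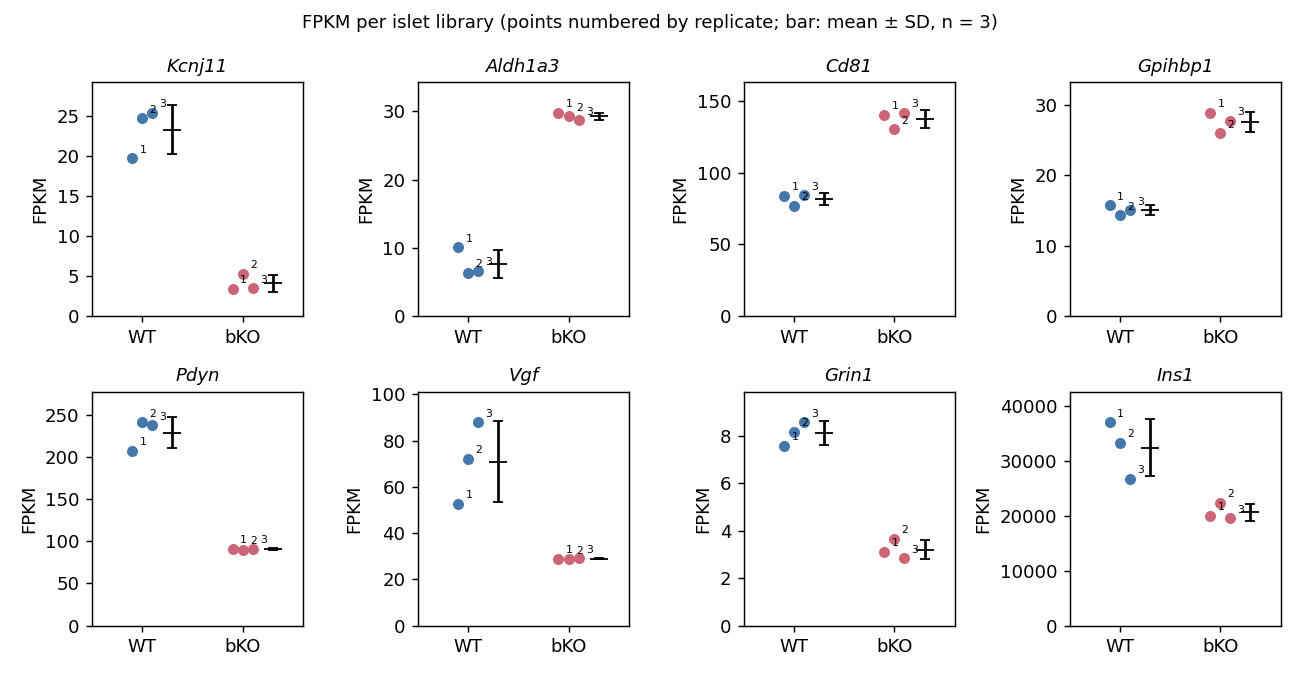
FPKM of 8 genes in each library (points, numbered by replicate) with the mean and SD of each group (n = 3) beside them. Kcnj11 lay at 3.45 to 5.31 FPKM in bKO and 19.7 to 25.4 in WT, Aldh1a3, Cd81 and Gpihbp1 were higher in every bKO library than in every WT library, and Pdyn, Vgf, Grin1 and Ins1 were lower.

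With the called genes included, 806 genes were higher and 1464 lower at an unadjusted p below 0.05, and 3144 genes (19.7%, where chance gives 10%) had no overlap between the groups. With bKO replicates 1 and 3 averaged as 1 sample the share was 23.3%, where chance gives 20%. The 31 calls rested on the set of libraries. With bKO replicates 1 and 3 averaged as 1 sample, limma called 0 genes, with 1238 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0765 for Pdyn. Leaving out WT replicate 1 gave 23 higher and 27 lower, WT replicate 2 gave 0 and 3, and WT replicate 3 gave 0 and 1. Leaving out bKO replicate 2 gave 3 and 6, and bKO replicate 1 or 3 gave 0 and 0. Without quantile normalization 19 genes were higher and 20 lower, so that the lower genes made up 51.3% of calls in place of 67.7%.

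Glucose and incretin signals reach insulin secretion through potassium and calcium channels and through G proteins, and the 1 gene called in these lists was Kcnj11. In the list of ATP-sensitive and other potassium channels, Kcnj11 was the 1 gene called of 19, over all genes and adjusted over the list alone. Kcnj8 and Abcc9, the pore and receptor of the vascular form of the channel, were at 7.78 ± 0.74 and 3.18 ± 0.39 FPKM in bKO against 5.04 ± 1.16 and 2.18 ± 0.29 in WT, with limma adjusted p of 0.221 and 0.230. Of 17 voltage-gated calcium and sodium channels, 13 G protein alpha subunits, 14 Gs-coupled receptors, 26 genes of the cAMP pathway and 16 RGS proteins, 0 passed over all genes and 0 adjusted over the list alone. Gnas, which encodes Gs alpha, was at 749 ± 25.5 and 750 ± 49.2 FPKM in WT and bKO (95% interval of the log2 difference -0.38 to 0.19). Gnaq was at 20.5 ± 0.14 and 21.1 ± 0.87 (-0.15 to 0.10). The fitted differences of Gnas and Gnaq, -0.10 and -0.03, turned positive without quantile normalization, and that of Gnaq also without bKO replicate 1, where it was 0.01. Glp1r and Gipr, the receptors of the incretins GLP-1 and GIP, were at 69.5 ± 7.93 and 8.43 ± 2.41 FPKM in WT and 79.8 ± 7.93 and 7.83 ± 0.95 in bKO, with limma adjusted p of 0.572 and 0.744. The sign for Gipr turned without WT replicate 1, where its log2 difference was 0.02. Vipr1 and Gcgr, receptors of VIP and glucagon, had log2 differences of -0.43 and -0.62 (limma adjusted p = 0.158 and 0.271).

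Of 13 Gq-coupled receptors, 0 passed over all genes and 2 were lower adjusted over the list alone. Ffar2, a receptor of short-chain fatty acids, was at 22.8 ± 2.01 FPKM in WT and 18.3 ± 0.64 in bKO, and P2ry1, a purine receptor, was at 4.74 ± 0.59 and 3.20 ± 0.36. In the phospholipase C and protein kinase C list, 0 of 24 passed over all genes, and 4 were lower and 1 higher adjusted over the list alone. The lower genes were the kinases Prkcb, with a log2 difference of -0.51, and Prkca, with -0.30, and the diacylglycerol kinases Dgkg, with -0.74, and Dgkb. The higher gene was Prkch, with 0.26. Neither list passed as a set, with camera adjusted p of 0.0934 and 0.824. The camera adjusted p of the other lists in the signalling groups was 0.737 for potassium channels, 0.661 for calcium and sodium channels, 0.312 for G protein alpha subunits, 0.641 for Gs-coupled receptors, 0.824 for the cAMP pathway and 0.571 for RGS proteins. Of 31 genes of calcium binding and calcineurin, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.943). The Gq-coupled list passed without quantile normalization (camera adjusted p = 0.0451) and without bKO replicate 2 (0.0471), with adjusted p = 0.724 with an estimated correlation over all 6 libraries.

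Mean levels of the insulin, amylin, glucagon and somatostatin genes were lower in bKO islets, and none passed a test. Ins1 was at 32443 ± 5194 FPKM in WT and 20701 ± 1531 in bKO, and Iapp, which encodes amylin, at 49657 ± 2028 and 34042 ± 5740 (SD, n = 3 each). Neither overlapped between the groups, which gives the smallest p that 3 against 3 allow (exact permutation test, two-sided, p = 0.1). Ins2 was at 233406 ± 39178 and 189918 ± 34537 FPKM (exact permutation test, two-sided, p = 0.2). Quantile normalization fixes the values of these most abundant genes, so they are given as deposited FPKM. Gcg, the gene of glucagon, was at 11381 ± 807 FPKM in WT and 10184 ± 2890 in bKO, and Sst, the gene of somatostatin, at 4969 ± 466 and 4162 ± 746. The lower means of Gcg and Sst came from bKO replicates 1 and 3, with Gcg at 8490 and 8540 FPKM and Sst at 3693 and 3772. In bKO replicate 2, Gcg was at 13521 FPKM, above every WT library, and Sst at 5022, within the WT range. Their log2 differences were -0.56 and -0.54 after quantile normalization (limma adjusted p = 0.478 and 0.341) and -0.19 and -0.27 without it (0.794 and 0.552). In the list of beta cell identity and maturity, 0 of 25 passed over all genes and 2 were lower adjusted over the list alone. Pcsk1, the convertase of proinsulin, was at 210 ± 16.2 FPKM in WT and 125 ± 27.0 in bKO, and G6pc2, the islet glucose-6-phosphatase, was at 670 ± 65.4 and 441 ± 31.9. Ucn3 had a log2 difference of -0.78, Slc2a2, the glucose transporter GLUT2, of -0.40, and Mafa, a transcription factor of mature beta cells, of 0.24 (limma adjusted p = 0.206, 0.478 and 0.669). Ins1, Ins2 and Iapp belong to this list, and quantile normalization set their log2 differences to 0 in the main fit. Without quantile normalization these were -0.64, -0.30 and -0.56. With the 3 genes held at 0, the list missed the threshold (camera adjusted p = 0.0681), with adjusted p = 0.854 with an estimated correlation. In camera at the preset correlation it passed without quantile normalization (0.00067), with median of ratios scaling (0.00261), without WT replicate 3 (0.00197) and without bKO replicate 2 (0.000813). Of 14 alpha cell markers and 10 delta and PP cell markers, 0 passed over all genes and 0 adjusted over the list alone, with camera adjusted p of 0.571 and 0.824. The alpha cell list passed as lower without bKO replicate 2 (0.0122), with adjusted p = 0.945 with an estimated correlation over all 6 libraries.

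Markers of progenitors and dedifferentiation lay higher in bKO islets as a set. Of 17 members, 2 rose over all genes, Aldh1a3 and Cd81, and 3 were higher adjusted over the list alone. Neurog3, the transcription factor of endocrine progenitors, was at 2.94 ± 0.72 FPKM in WT and 4.40 ± 0.38 in bKO (limma adjusted p = 0.280). The set passed in camera (adjusted p = 0.000231) and in fry (0.00805), with adjusted p = 0.164 with an estimated correlation. With bKO replicates 1 and 3 averaged, fry gave an adjusted p of 0.0763. All 20 beta cell disallowed genes, which are silenced in mature beta cells and active in most other cells, had positive differences with a median of 0.37. Of them, 0 passed over all genes and 0 adjusted over the list alone. This set passed in camera (adjusted p = 3.87e-06), with adjusted p = 0.624 with an estimated correlation. Its medians were 0.50 and 0.53 in bKO replicates 1 and 3 and 0.05 in bKO replicate 2, against -0.20 to 0.17 in WT. The acinar medians of the same libraries were 1.82, 1.80 and 0.68.

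Genes of the unfolded protein response and of exocytosis lay lower in bKO islets as sets, and immediate early genes higher. In the unfolded protein response list, 24 of 30 members had negative differences, with a median of -0.20. Over all genes 0 passed, and adjusted over the list alone 13 were lower and 1 was higher. Among the lower were Pdia6, a disulfide isomerase, at 255 ± 30.5 FPKM in WT and 191 ± 5.60 in bKO, and Manf, a secreted factor of the endoplasmic reticulum, at 92.8 ± 7.77 and 75.9 ± 4.15. Herpud1, a gene of protein degradation at that membrane, was at 114 ± 0.28 and 93.8 ± 6.37. The higher member was Txnip, a glucose-responsive inhibitor of thioredoxin, at 44.6 ± 8.79 and 76.6 ± 6.96. The set passed as lower (camera adjusted p = 1.90e-05), with adjusted p = 0.624 with an estimated correlation. Of 33 genes of exocytosis, 0 passed over all genes and 3 were lower adjusted over the list alone. These were Syt4, a synaptotagmin, with a log2 difference of -0.61, Scg3, a granin, with -0.57, and Pcsk1 with -0.77. That set passed as lower (camera adjusted p = 0.0320), with adjusted p = 0.853 with an estimated correlation. It missed the threshold without WT replicate 1 (0.326), bKO replicate 1 (0.0939) or bKO replicate 3 (0.158) and with bKO replicates 1 and 3 averaged (0.135). The exocytosis medians were -0.20 and -0.22 in bKO replicates 1 and 3, where acinar medians were 1.82 and 1.80, and 0.03 in bKO replicate 2, within the WT range of -0.13 to 0.12.

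Of 24 calcium-dependent immediate early genes, 20 had positive differences, 0 passed over all genes and 1, Jun, was higher adjusted over the list alone. Jun was at 33.1 ± 2.49 FPKM in WT and 49.6 ± 5.78 in bKO. Egr2 had a log2 difference of 0.39 and Nr4a2 one of -0.70 (limma adjusted p = 0.202 and 0.240). The set passed as higher (camera adjusted p = 8.41e-06), with adjusted p = 0.643 with an estimated correlation. Its median in bKO replicate 2, 0.13, lay within the WT range of -0.17 to 0.20, and those of bKO replicates 1 and 3 were 0.29 and 0.28. The acinar medians of bKO replicates 1, 2 and 3 were 1.82, 0.68 and 1.80, and WT replicate 1 had the lowest WT median of both lists. Of 29 cell cycle genes, 23 had positive differences, 0 passed over all genes and 1, Cdkn2a, named after its values were seen, was lower adjusted over the list alone. The cell cycle set passed as higher (camera adjusted p = 0.00988), with adjusted p = 0.837 with an estimated correlation. It missed the threshold without WT replicate 2 (0.104), WT replicate 3 (0.0543) or bKO replicate 1 (0.0870) and with bKO replicates 1 and 3 averaged (0.0531). Cell cycle medians were 0.22 and 0.23 in bKO replicates 1 and 3, where stellate and fibroblast medians were both 0.82, and -0.05 in bKO replicate 2, within the WT range of -0.10 to 0.12. Glycolysis with 23 genes, oxidative phosphorylation with 36 and the interferon response with 28 had 0 genes passing over all genes and 0 adjusted over the list alone, and camera adjusted p of 0.320, 0.0768 and 0.953. Oxidative phosphorylation, with adjusted p = 0.853 with an estimated correlation, passed as lower at the preset correlation without quantile normalization (0.00607), with median of ratios scaling (0.000163), without WT replicate 3 (0.0179) and without bKO replicate 2 (0.0151). The interferon list passed as higher without WT replicate 1 (0.00366), with adjusted p = 0.984 with an estimated correlation over all 6 libraries.

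Markers of endothelial cells, which line the islet capillaries, were higher in bKO islets as a set. All 17 members had positive differences with a median of 0.39, and 16 had no overlap between the groups. Over all genes 2 rose, Cd34 from 6.90 ± 0.24 to 11.9 ± 0.60 FPKM and Egfl7 from 28.3 ± 1.06 to 42.0 ± 0.61, and adjusted over the list alone 15 were higher. Robo4 and Tie1, receptors of endothelial cells, were at 5.07 ± 0.17 and 5.26 ± 0.27 FPKM in WT and at 8.15 ± 0.57 and 8.13 ± 0.38 in bKO. The medians per library were 0.39, 0.42 and 0.39 in bKO replicates 1, 2 and 3 and lay between -0.05 and 0.06 in WT. The set passed in camera (adjusted p = 4.81e-17) and was the 1 list of the 28 tested that held with an estimated correlation (adjusted p = 0.0377 with an estimated correlation). That call was lost with bKO replicates 1 and 3 averaged (adjusted p = 0.107 with an estimated correlation). Fry, which does not compare the list with other genes, gave the endothelial set an adjusted p of 0.00217, and of 0.0273 with the pair averaged. Markers of macrophages and other leukocytes lay lower, with negative differences in 19 of 20 and a median of -0.29. Over all genes 0 passed, and adjusted over the list alone 4 were lower, among them Cd68, a lysosomal protein of macrophages, at 20.4 ± 2.87 FPKM in WT and 14.0 ± 1.22 in bKO, and C1qa, a complement component, at 43.2 ± 10.3 and 26.4 ± 3.36. The macrophage set passed as lower in camera (adjusted p = 4.82e-05) and fry (0.0275), with adjusted p = 0.164 with an estimated correlation. With bKO replicates 1 and 3 averaged, the fry adjusted p of the macrophage set was 0.130.

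Markers of exocrine and stromal cells varied between the libraries of a group. All 24 acinar markers and all 21 markers of stellate cells and fibroblasts had positive differences, with medians of 1.36 and 0.54. Of these, 0 passed over all genes and 0 adjusted over the list alone. Pnlip, pancreatic lipase, was at 86.3 ± 72.4 FPKM in WT and 194 ± 90.7 in bKO, and Mgp, a matrix protein of fibroblasts, at 80.8 ± 21.2 and 125 ± 16.1. The sets passed as higher (camera adjusted p = 1.90e-05 and 3.87e-06), with adjusted p = 0.837 and 0.831 with an estimated correlation. The acinar set missed the threshold without WT replicate 1 (0.154). Of 15 duct markers, 13 had positive differences and 0 passed over all genes or adjusted over the list alone. The duct set passed as higher (camera adjusted p = 0.0183), with adjusted p = 0.624 with an estimated correlation. It missed the threshold without quantile normalization (0.107), with median of ratios scaling (0.0514), without bKO replicate 1 (0.0707) and with bKO replicates 1 and 3 averaged (0.0531). Neural and Schwann cell markers, with 0 of 12 passing over all genes and 0 adjusted over the list alone, had a camera adjusted p of 0.198. They passed as higher without WT replicate 1 (0.000195), with adjusted p = 0.853 with an estimated correlation over all 6 libraries. Of 7 adipocyte markers, 0 passed over all genes. Adjusted over the list alone, Fabp4, a fatty acid carrier also made by capillaries, was higher with a log2 difference of 0.78 and Lpl, lipoprotein lipase, was lower with -0.67. The camera adjusted p was 0.953. The red blood cell list had 2 tested genes and was not tested as a set.

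**Figure D3:**
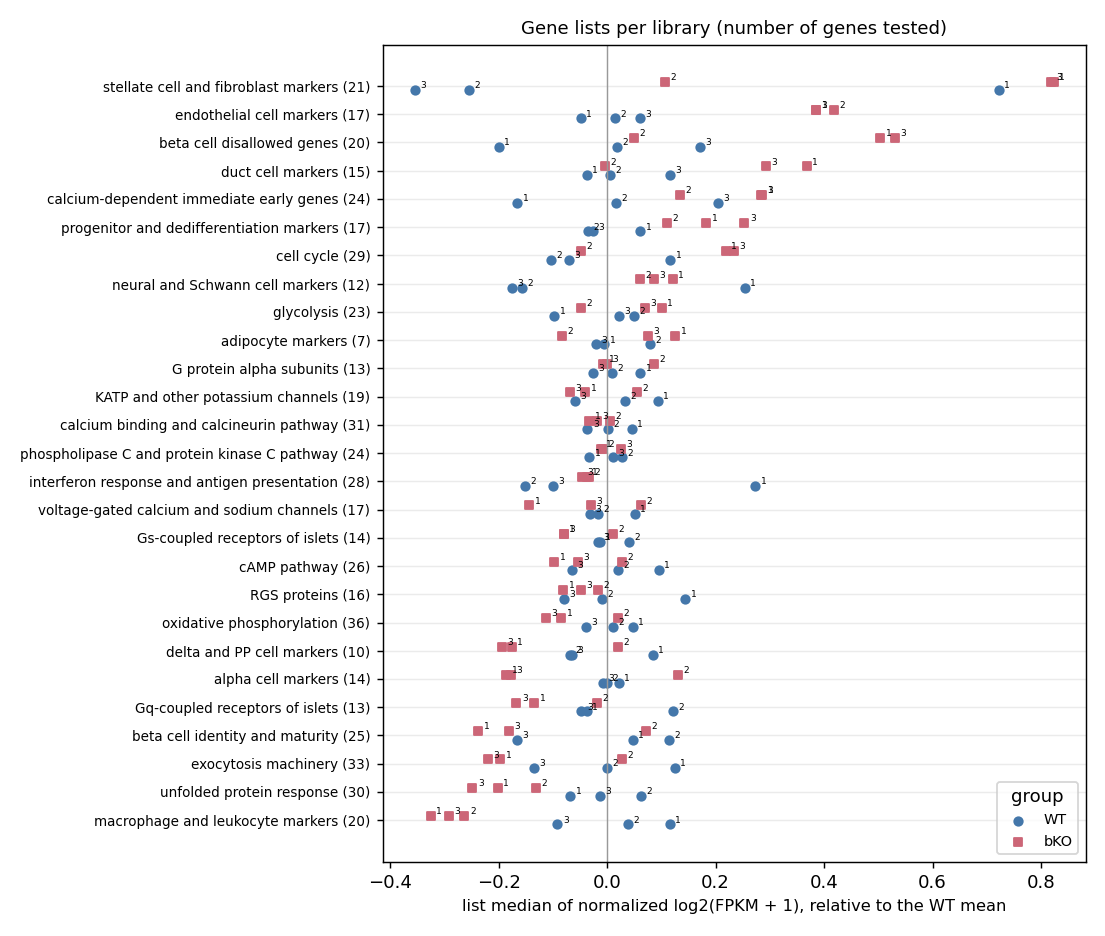
Median over the members of each gene list of quantile normalized log2(FPKM + 1), relative to the WT mean, for each library (WT circles, bKO squares, numbered by replicate), with the number of tested genes in parentheses. Acinar markers, whose medians ran from -2.35 to 1.82, and the red blood cell list are left out, and the endothelial medians of the bKO libraries lay at 0.39 to 0.42.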

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

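The average of bKO replicates 1 and 3 as 1 sample was chosen after the data were seen, and the other settings before. The counts of 10 higher and 21 lower genes stayed within 1.5 times with a pseudocount of 0.1, median of ratios scaling, no filter on 0, a mean FPKM of at least 1 and eBayes without trend. Without quantile normalization 19 were higher. With the pair averaged 0 were higher and 0 lower in limma (1238 at an unadjusted p below 0.05). The log2 difference of Kcnj11 was -2.26 with an adjusted p of 0.211, against 0.0185 to 0.228 over all its alternatives. With the replicate number as a block, 0 were higher and 0 lower in limma (2343 at an unadjusted p below 0.05), and Kcnj11 stayed at -2.35 with an adjusted p of 0.0788. The block put the Gq-coupled receptors and beta cell identity past the threshold (camera adjusted p = 0.0430 and 0.0143), with adjusted p = 0.724 and 0.854 with an estimated correlation and no block. Whether the numbers pair the samples stays open. Deviations of same-numbered libraries correlated at -0.226, 0.0537 and 0.346, and those of differently numbered libraries at -0.403 to 0.337. As bKO replicates 1 and 3 were nearly alike, these values cannot settle it. With 1 library left out the higher genes ranged from 0 to 23, the lower from 0 to 27, Kcnj11 from -2.52 to -2.26 and the lists past the threshold from 8 to 15. Of the 11 lists past the threshold, 1 was left with an estimated correlation and 3 with fry. Fewer libraries in the averaged and left-out fits leave fewer degrees of freedom, and for the other changes the cause was not tested. The direction turned for Gnas (0.00098) and Gnaq (0.037) without quantile normalization. None of the 11 lists past the threshold turned under these settings. By camera adjusted p, the direction turned for potassium channels (0.806), adipocyte markers (0.946) and the interferon response (0.986) at a mean FPKM of at least 1, for the interferon response with the block (0.912), and for the cAMP pathway with the pair averaged (0.966). With 1 library left out the direction turned for Abcc8 (-0.031 to 0.16), Gipr (-0.37 to 0.019) and Gnaq (-0.055 to 0.0070), and for these lists by camera adjusted p: RGS proteins (0.217 to 0.877), adipocyte (0.605 to 0.988), alpha cell (0.0122 to 0.957), cAMP pathway (0.235 to 0.957), calcium binding (0.605 to 0.996), delta and PP cell (0.382 to 0.957), interferon (0.00366 to 0.957), protein kinase C (0.326 to 0.889) and voltage-gated channels (0.141 to 0.957). Settings that kept 6 libraries or averaged the pair gave 496 values of 62 named genes. Of these, 449 kept direction and side of the threshold, 44 lost the threshold, 1 gained it and 2 turned. Most of these genes were not called in the main fit and could not lose the threshold, so 449 overstates how well the calls held. With 1 library left out, 273 of 372 values of these genes kept both, 93 lost the threshold, 2 gained it and 4 turned. For the 28 lists, 245 of 280 values under the former settings kept both, 23 lost the threshold, 7 gained it and 5 turned. With 1 library left out, 138 of 168 list values kept both, 8 lost the threshold, 7 gained it and 15 turned. The authors' own normalized columns were not run, because the table used here holds FPKM columns only, and for the same reason no deposited comparison was set beside the fit. Depth, about 22800000 to 39300000 fragments, limits genes of low FPKM most.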

Other observations

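The tests of explanations and of the added gene lists here were all chosen after the results were seen. Outside the lists fixed beforehand, 3 lists were added, and most of their members had negative differences in bKO islets. The lists were prompted by single genes of low p in these same libraries, which were left out of the tests. Genes that move together share the deviation of the genes left out, so the tests are not independent of that choice. Genes of signal peptide processing and translocation, which bring secreted proteins into the endoplasmic reticulum, had negative differences in 28 of 28, with a median of -0.16 and medians per library of -0.17, -0.09 and -0.19 in bKO replicates 1, 2 and 3 against -0.03 to 0.05 in WT. Lysosomal enzymes had negative differences in 29 of 32 with a median of -0.17, and genes of cholesterol synthesis in 19 of 21 with a median of -0.19. Lysosomal medians were -0.21, -0.13 and -0.22 in bKO replicates 1, 2 and 3, where macrophage and leukocyte medians were -0.33, -0.26 and -0.29. A link between lysosomal enzymes and macrophage markers was not tested. In camera the adjusted p over the 3 added lists was 5.66e-09 for signal peptide processing, 5.66e-09 for lysosomal enzymes and 0.000216 for cholesterol synthesis. The adjusted p with an estimated correlation was 0.151 for signal peptide processing, 0.120 for lysosomal enzymes and 0.331 for cholesterol synthesis, so that a shared decrease remains a hypothesis. The medians of cholesterol synthesis overlapped between the groups, from -0.25 to 0.29 in WT and -0.23 to -0.10 in bKO.

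The higher endothelial markers in bKO islets were weighed against a change in the mix of cells. A lower share of beta cells as the only change would raise the markers of every other cell type. The macrophage list had a median of -0.289, with no overlap between the groups. The alpha cell list and the delta and PP cell list had medians of -0.09 and -0.075, and their medians per library overlapped between the groups. The acinar, duct, stellate, neural and adipocyte lists had medians above 0. Macrophage markers could also fall on their own, so the macrophage list cannot exclude a lower share of beta cells beside another change. Carry-over of exocrine tissue or of stroma as the whole cause was argued against by fits with the acinar or the stellate score as a covariate, in which the endothelial median was 0.373 and 0.444. The 95% intervals of the list mean over the libraries in these fits were 0.31 to 0.44 and 0.36 to 0.55. Both fits counted bKO replicates 1 and 3 separately, so the intervals may be too narrow if the pair share a source. Acinar medians were set apart mostly by WT replicate 1, at -2.35 against 0.68 to 1.82 in the other libraries. More endothelial cells, more RNA in each, the genotype and the picking of the islets stay open and were not tested.

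The higher beta cell disallowed genes in bKO islets rested on bKO replicates 1 and 3, since the median of bKO replicate 2 was 0.0494, within the WT range. RNA of acinar cells could account for part of the difference, as the median was 0.173 with the acinar score as a covariate against 0.37 without it. With the stellate score it was 0.344, and in both fits 20 of 20 members stayed positive and the list passed (camera adjusted p = 0.00112 and 0.00016). The 95% intervals of the list mean over the libraries were -0.32 to 0.73 and -0.44 to 1.05, which hold both 0 and the difference without a covariate, so that RNA of other cells and an effect of the genotype cannot be told apart.

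In the same fits the exocytosis median was -0.14 without a covariate, -0.03 with the acinar score and -0.13 with the stellate score (camera adjusted p = 0.832 and 0.138), with 95% intervals of the list mean over the libraries of -0.36 to 0.24 and -0.63 to 0.33. The cell cycle median was 0.15 without a covariate, 0.16 with the acinar score and 0.0063 with the stellate score (camera adjusted p = 0.00138 and 0.851), with intervals of -0.22 to 0.56 and -0.15 to 0.13. For immediate early genes it was 0.21, 0.12 and 0.27 (camera adjusted p = 0.0103 and 4.40e-07), with intervals of -0.14 to 0.32 and -0.21 to 0.80. For duct markers it was 0.26, 0.053 and 0.088 (camera adjusted p = 0.0921 and 0.103), with intervals of -0.15 to 0.35 and -0.29 to 0.84.

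Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 31 genes and the highest of the others 106, and 2 of the 10 splits, the real one included, gave at least 31. The split with 106 genes set WT replicate 1 and bKO replicates 1 and 3 against the rest, and points to a structure of the samples other than genotype. Stellate and fibroblast medians in those libraries were 0.72, 0.82 and 0.82. They were -0.25, -0.35 and 0.11 in WT replicates 2 and 3 and bKO replicate 2. For gene lists the real split gave 11 and the highest of the others 14, and 3 of the 10 splits, the real one included, gave at least 11. At an unadjusted p below 0.05 the real split gave 2270 genes, and the split of WT replicates 1 and 2 and bKO replicate 2 against the rest gave 3123, with 13 lists. Insulin transcripts took 36.1%, 37.4% and 33.5% of FPKM in WT replicates 1 and 2 and bKO replicate 2. The share was 29.8%, 27.3% and 26.4% in WT replicate 3 and bKO replicates 1 and 3. Whether the mix of cells accounts for either split was not tested.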
